A study of Homo sapiens with 24 samples.

How the data were processed

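Gene expression was measured by 3′ RNA sequencing, which reads a stretch near the polyadenylated end of each transcript, in 2 established human multiple myeloma cell lines, MM1.S (labelled p53 wild type) and JJN3 (labelled p53 null). The 4 treatments, each of 24 h, were vehicle, CX-5461 at 500 nM, panobinostat at 50 nM, and both, giving 8 groups of 3 libraries. CX-5461 inhibits transcription of ribosomal RNA genes by RNA polymerase I, and panobinostat inhibits histone deacetylases (HDACs). Per the labels' protocols, the cells were grown in RPMI-1640 medium, total RNA was isolated with a Qiagen RNeasy kit, and libraries were made from polyA-selected RNA with an Illumina TruSeq kit. Each library was assigned to its line, drug and replicate number from its title. The labels do not say whether the replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical. PolyA selection leaves out ribosomal RNA, so the transcripts made by RNA polymerase I were not measured.

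The authors deposited 1 table of raw counts per cell line, whole numbers of reads per gene with no normalisation. The values and the labels are the source of this statement of the unit. Per the submitters' processing notes, the tools were HISAT2 2.2.1, featureCounts 2.0.1 and limma 3.50.0 and the genome builds hg19 and GRCh37, with no role or order given. The annotation, the strand setting and the handling of reads that map to several places are not given in the sources used here. A gene and an antisense partner can therefore not be told apart. Values of genes with near-identical copies (metallothioneins, histones, ribosomal proteins, HLA-DQ genes, CCL3) are uncertain. The tables name genes by NCBI Gene identifier, and both list the same 28395 identifiers. Symbols were taken from a table of human gene names on the assembly GRCh38.p14, used for names alone, and 27745 identifiers matched. The other 650 held at most 0.039% of the counts of a library. No coordinates are given, because the assembly of that table is not among the builds of the processing notes.

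Total counts per library ranged from 4751893 to 7305069 (median 5551875), and 19937 genes in MM1.S and 18732 in JJN3 had at least 1 count. At these depths a count of 0 in 1 JJN3 library allows up to 0.631 CPM, taking 3 counts as the limit. Reads carry no molecular identifiers, so intervals and limits of this kind cover counting error only. The counts of replicate pairs differed by more than sampling noise in every group, and each library was used as 1 replicate.

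Differential expression was tested with edgeR 4.0.16 in R 4.3.3: counts were scaled by TMM, genes with low counts were removed by filterByExpr at its default settings, dispersions were estimated robustly, and contrasts were tested by the quasi-likelihood F test (glmQLFit and glmQLFTest, two-sided) with Benjamini-Hochberg adjustment. Genes with an adjusted p under 0.05 are called higher or lower. Each line was fitted on its 12 libraries as 4 group means (8 residual degrees of freedom), with 12030 genes tested in MM1.S and 11411 in JJN3. The common biological coefficient of variation was 0.107 in MM1.S and 0.154 in JJN3. The effect of each treatment in JJN3 minus its effect in MM1.S was tested in 1 fit of 24 libraries and 8 group means (12872 genes). Departure from additivity is the log2 fold change of the combination minus the sum of the log2 fold changes of the single drugs, all against vehicle. Log2 fold changes are given ± their standard error, computed from the F statistic, and expression levels as mean CPM (counts scaled to library size) ± SD over the 3 libraries of a group. Where all libraries of a group had 0 counts, the fold is given as a lower bound against 3 counts over the group. With 1 to 3 counts over the group it is given as a ratio with its 95% counting interval.

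Gene groups were 35 lists of known targets, pathways and cell type markers. They were fixed before the data were examined, as were the comparisons, the tests and the rule for named genes. Lists with at least 5 tested members were tested with camera (limma 3.58.1) with a preset correlation of 0.01 between genes, adjusted over the lists of a comparison, and again with the correlation estimated from the data. Members are counted as higher or lower by the edgeR test over all genes and, in the words "adjusted over the list alone", after adjustment over the members of the list. Genes are named by rule. For a treatment against vehicle these are the 5 genes with the largest rises and the 5 with the largest falls among those called, with an average log2 CPM of at least 3 and all treated libraries above (below) all vehicle libraries, which chance gives for 10% of genes with 3 against 3. The 2 members of each called list with the smallest adjusted p in its direction, and a panel of 26 genes, were added. For the other comparisons the rule takes 3 rises, 3 falls and the panel genes called. Genes without a symbol and pseudogenes were passed over, and some named genes are not reported here.

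The replicate numbers were checked for pairing by the correlation of the deviations of the libraries from their group means. In JJN3 the 18 correlations between libraries of the same number were 0.201 to 0.485 (median 0.328), against -0.337 to -0.00791 (median -0.168) for libraries of different numbers. The numbers therefore pair the JJN3 libraries, as a finding from the data and not from the labels, and the result of a fit with the replicate number as a block is given where it changes a call in JJN3 or moves a count by over 1.5 times.

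The fits were tested on simulated counts with 200 genes changed by known amounts. The counts for the shares given here were drawn without the pairing found in JJN3. Shares that involve JJN3 may therefore differ from those for the real libraries. For CX-5461 against vehicle, edgeR recovered 50.8%, 81.8% and 96.9% of genes changed 1.5-fold, 2-fold and 4-fold in MM1.S (11691 genes) and 16.7%, 71.2% and 95.4% in JJN3 (11191 genes). For departure from additivity it recovered 10.8%, 58.5% and 86.2% in MM1.S (11689 genes) and 3.03%, 31.3% and 72.7% in JJN3 (11186 genes), and for the difference of the CX-5461 effect between the lines 4.84%, 44.4% and 89.2% (12287 genes). The list test called 0 of 20 unchanged simulated lists in each line.

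Alternatives were the size factors of DESeq2 (RLE) and library size alone as scaling, no expression filter, a filter of CPM 1 in 3 libraries, DESeq2 1.42.0, limma-voom, fits of the compared groups alone, the replicate block, fry, and fits without each library in turn. Overlaps between calls were compared with the product of the list lengths over the genes tested and, for drugs that share vehicle libraries, with 50 simulations of unchanged groups. Splits of the libraries into other groups were counted in the same fits. Levels of ribosomal RNA, protein levels, cell numbers and viability were not analysed here.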

Results

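The series set CX-5461 and panobinostat, alone and together, against vehicle in myeloma cells with and without p53, to look for transcriptional changes behind the joint action of the drugs. MM1.S and JJN3 are human multiple myeloma lines, that is, malignant plasma cells, and each was sampled by 3′ RNA sequencing after 24 h in 4 groups of 3 libraries. Mean total counts per group ranged from 5187385 ± 235458 with panobinostat to 6959579 ± 366051 with CX-5461 in MM1.S, and from 5361461 ± 772893 with panobinostat to 5915346 ± 685957 with vehicle in JJN3 (SD, n = 3). The first principal component held 82.3% of the variance in MM1.S and 63.0% in JJN3, and in both lines it parted the libraries with panobinostat from those without. On the second component of JJN3 (8.51% of the variance) the 4 libraries of replicate 2 stood apart, at -25.6 to -13.9, from the other 8.

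**Figure D1:**
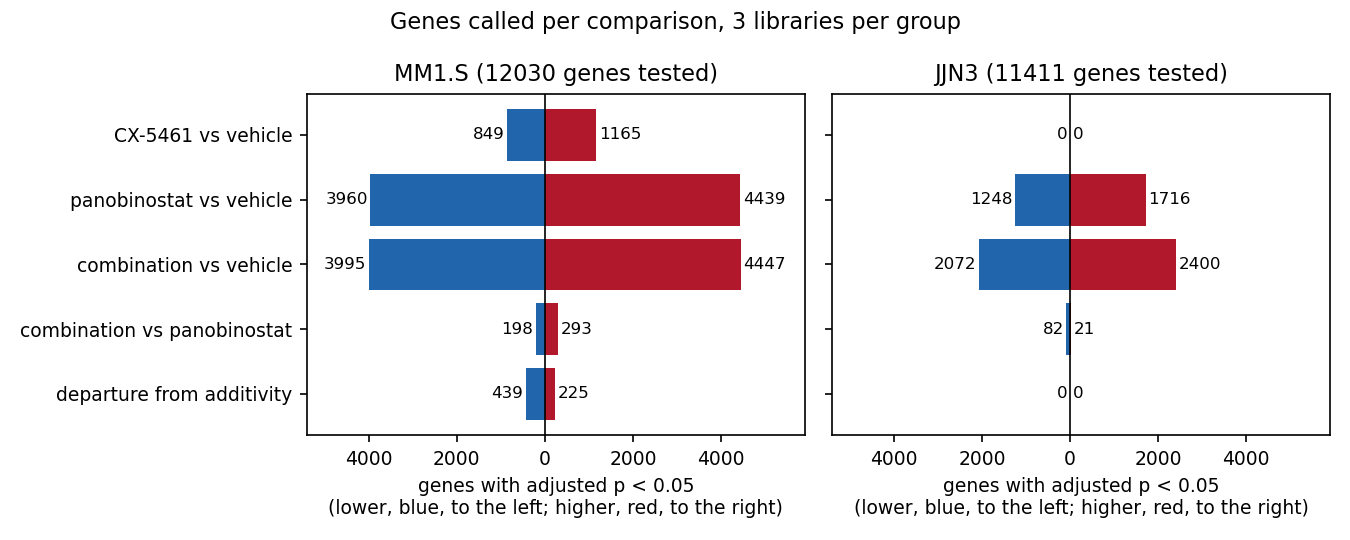
Number of genes called lower (blue, left) and higher (red, right) by edgeR at an adjusted p under 0.05 in each of 5 comparisons, for MM1.S and JJN3. The comparisons with panobinostat in 1 group alone hold 2964 to 8442 genes, and CX-5461 against vehicle holds 2014 in MM1.S and 0 in JJN3.

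CX-5461 raised the targets of p53 in MM1.S. Of 49 targets tested, 38 rose and 0 fell, or 43 and 0 adjusted over the list alone, with a median log2 fold change of 1.52 (camera adjusted p = 4.99e-98, adjusted p = 5.27e-07 with an estimated correlation). CDKN1A (NCBI Gene 1026), which encodes the cell cycle inhibitor p21, rose from 46.0 ± 6.60 to 734 ± 47.6 CPM (SD, n = 3, log2 fold change 3.99 ± 0.14, edgeR adjusted p = 1.12e-16). MDM2 (NCBI Gene 4193), the ubiquitin ligase that marks p53 for degradation, rose from 347 ± 57.7 to 1449 ± 65.8 CPM. PHLDA3, an inhibitor of AKT, rose from 19.5 ± 7.47 to 317 ± 11.5 CPM, and DDB2, a sensor of DNA damage in nucleotide excision repair, from 33.0 ± 2.60 to 195 ± 5.48 CPM. GDF15, a cytokine of the stress response, showed the largest rise, from 0.396 ± 0.350 to 50.4 ± 5.68 CPM (log2 fold change 6.81 ± 0.35).

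Pro-apoptotic members of the BCL2 family rose with CX-5461 in MM1.S, 6 of 9 tested and 0 lower, also adjusted over the list alone (median log2 fold change 1.16, camera adjusted p = 3.31e-10, adjusted p = 0.00272 with an estimated correlation). BBC3 (PUMA, NCBI Gene 27113) rose from 80.6 ± 12.7 to 453 ± 40.9 CPM and PMAIP1 (NOXA) by 2.71 ± 0.27 on the log2 scale. The anti-apoptotic genes BCL2 and MCL1 had log2 fold changes of 0.13 ± 0.14 and 0.03 ± 0.09 and did not pass (edgeR adjusted p = 0.585 and 0.893). Of 9 anti-apoptotic regulators 2 rose and 0 fell (camera adjusted p = 0.127). Targets of NF-kB, the inflammatory transcription factor, rose, 9 of 21 with 1 lower, or 12 and 1 adjusted over the list alone (camera adjusted p = 1.01e-07, adjusted p = 0.0236 with an estimated correlation). RELB was at 1.43 ± 0.11 on the log2 scale. Interferon-stimulated genes rose, 10 of 35 with 0 lower, or 12 and 0 adjusted over the list alone (median 0.39, or 0.33 with genes absent from 1 group at their bound, camera adjusted p = 1.54e-04, adjusted p = 0.0199 with an estimated correlation), among them CXCL10 (3.11 ± 0.32) and IFIT3 (2.51 ± 0.32). Of 20 immediate early genes, the first genes induced by growth and stress signals, 10 rose and 2 fell, or 11 and 2 adjusted over the list alone (median 0.88, or 0.63 with such genes at their bound, camera adjusted p = 1.05e-04, adjusted p = 0.0316 with an estimated correlation). JUN rose from 83.8 ± 21.1 to 313 ± 22.5 CPM.

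Genes of protein secretion and of cholesterol synthesis fell with CX-5461 in MM1.S. Of 47 chaperone and secretion genes of the endoplasmic reticulum (ER), 33 fell and 0 rose, or 39 and 1 adjusted over the list alone (median -0.47, camera adjusted p = 4.79e-22, adjusted p = 0.0199 with an estimated correlation). PDIA4, a disulphide isomerase, fell from 443 ± 3.80 to 211 ± 29.3 CPM and HSPA5, the main ER chaperone, had a log2 fold change of -0.87 ± 0.12. Of 23 genes of cholesterol synthesis, 13 fell and 0 rose, or 13 and 1 adjusted over the list alone (median -0.59, camera adjusted p = 3.41e-11, adjusted p = 0.0435 with an estimated correlation). MSMO1, a sterol oxidase, was at -1.33 ± 0.14 on the log2 scale. Ribosome biogenesis genes were lower for 23 of 68 members and higher for 0, or 34 and 0 adjusted over the list alone (median -0.32, camera adjusted p = 1.06e-10), a call that was lost with an estimated correlation (adjusted p = 0.155). NOP16, a nucleolar protein, fell, with a log2 fold change of -0.86 ± 0.12. MYC, the growth-promoting transcription factor (NCBI Gene 4609), fell from 42.5 ± 9.75 to 20.5 ± 4.12 CPM (log2 fold change -1.06 ± 0.18, edgeR adjusted p = 1.64e-04), and 12 of 43 MYC targets were lower and 2 higher (17 and 2 adjusted over the list alone, camera adjusted p = 6.03e-04, adjusted p = 0.224 with an estimated correlation). IRF4, a transcription factor on which myeloma cells depend (NCBI Gene 3662), fell from 298 ± 13.9 to 124 ± 5.74 CPM, and 7 of 20 plasma cell identity genes were lower and 2 higher (9 and 4 adjusted over the list alone, camera adjusted p = 0.00217, adjusted p = 0.277 with an estimated correlation). Of 20 genes of the RNA polymerase I machinery 1 was higher and 3 lower (camera adjusted p = 0.102). UBTF, its upstream binding factor, had a log2 fold change of -0.23 ± 0.12 and the catalytic subunit POLR1A of -0.36 ± 0.20, and neither passed (edgeR adjusted p = 0.210 and 0.223).

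DNA replication genes were higher with CX-5461 in MM1.S, 29 of 49 with 0 lower, or 33 and 0 adjusted over the list alone (median 0.50, camera adjusted p = 4.12e-13, adjusted p = 0.136 with an estimated correlation). TK1, thymidine kinase, rose from 57.3 ± 6.10 to 143 ± 22.2 CPM and CDT1, a licensing factor of replication, by 0.96 ± 0.12 on the log2 scale. Repair genes were higher for 16 of 46 members and lower for 2, or 19 and 2 adjusted over the list alone (camera adjusted p = 2.76e-04, adjusted p = 0.136 with an estimated correlation). Genes of mitosis (G2/M) went both ways, 6 higher and 10 lower of 50, or 7 and 12 adjusted over the list alone. Their median was 0.01, their mean -0.08 and the test pointed down (camera adjusted p = 0.236). CCNB1, cyclin B1, was at -0.70 ± 0.14. Targets of the integrated stress response were higher for 13 of 39 members and lower for 2, or 14 and 2 adjusted over the list alone (camera adjusted p = 1.33e-05, adjusted p = 0.437 with an estimated correlation). DDIT3 (CHOP), its pro-apoptotic transcription factor, rose from 5.16 ± 2.22 to 40.6 ± 4.73 CPM. The topoisomerase gene TOP2B fell, with a log2 fold change of -0.50 ± 0.10, while TOP2A was at 0.19 ± 0.11 (edgeR adjusted p = 0.272). The largest falls by the rule were those of PIF1, a DNA helicase, from 25.2 ± 2.72 to 5.83 ± 1.80 CPM, and of FRMD3 (-1.47 ± 0.29) and MSMO1.

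In all, edgeR called 2014 of 12030 genes for CX-5461 against vehicle in MM1.S, 1165 higher and 849 lower, of which 404 and 55 changed at least 2-fold. With library size alone as scaling the split was 1544 higher and 509 lower, that is, 75.2% higher in place of 57.8%. Lists with smaller shifts, whose calls were lost with an estimated correlation, are described among the other observations.

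With CX-5461 in JJN3, edgeR called 0 of 11411 genes. At an unadjusted p under 0.05 it gave 633 genes, limma-voom called 0, and DESeq2 called 18, 3 higher and 15 lower. With the replicate number as a block edgeR called 157, 69 higher and 88 lower, and without vehicle replicate 2 it called 2. Of 43 p53 targets tested 0 were called (median log2 fold change 0.02, camera adjusted p = 0.409). CDKN1A had 36.0 ± 10.9 CPM with CX-5461 and 26.0 ± 3.70 with vehicle (SD, n = 3, log2 fold change 0.46 ± 0.20, edgeR adjusted p = 0.851), and MDM2 and BBC3 had log2 fold changes of 0.07 ± 0.16 and -0.32 ± 0.20 (edgeR adjusted p = 0.994 and 0.948). Ribosome biogenesis genes lay lower as a list, although 0 of 68 members passed (1 lower adjusted over the list alone, median -0.19, camera adjusted p = 2.07e-10, adjusted p = 0.542 with an estimated correlation). NCL, the nucleolar protein nucleolin, was at -0.45 ± 0.10 (edgeR adjusted p = 0.301, 0.00106 with the block) and NPM1, nucleophosmin, at -0.38 (edgeR adjusted p = 0.542, 0.00404 with the block). Targets of the integrated stress response also lay lower with 0 of 39 called, also adjusted over the list alone (median -0.25, camera adjusted p = 7.64e-06, adjusted p = 0.542 with an estimated correlation). ASNS, asparagine synthetase, was at -0.46 (edgeR adjusted p = 0.570, 0.0255 with the block), and MHC class II genes lay higher with 0 of 8 called, or 2 adjusted over the list alone (median 0.26, camera adjusted p = 0.00371, adjusted p = 0.542 with an estimated correlation). INSIG1, a regulator of cholesterol synthesis, was at -0.62 (edgeR adjusted p = 0.363, 1.71e-05 with the block).

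The response to CX-5461 differed between the lines for the p53 targets. The log2 fold change in JJN3 minus that in MM1.S was below 0 for 25 of 49 targets and above 0 for 0 at the threshold, or 30 and 0 adjusted over the list alone (median -1.30, camera adjusted p = 1.04e-75, adjusted p = 1.89e-10 with an estimated correlation). The difference was -3.53 ± 0.24 for CDKN1A, -1.99 ± 0.21 for MDM2, -2.81 ± 0.23 for BBC3 and -3.28 ± 0.33 for DDIT3, and in the other direction 1.31 ± 0.19 for IRF4, which fell in MM1.S. Of 9 pro-apoptotic BCL2 family genes 2 differed, or 5 adjusted over the list alone, all smaller in JJN3 (median -0.66, camera adjusted p = 1.21e-10, adjusted p = 4.86e-05 with an estimated correlation), and of 23 cholesterol synthesis genes 3 differed, or 9 adjusted over the list alone, all above 0 (median 0.33, camera adjusted p = 1.61e-07, adjusted p = 0.0233 with an estimated correlation). Among 12872 genes edgeR called 170, 37 above 0 and 133 below, 582 with the replicate number as a block (210 and 372), and 108 without MM1.S vehicle replicate 1.

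**Figure D2:**
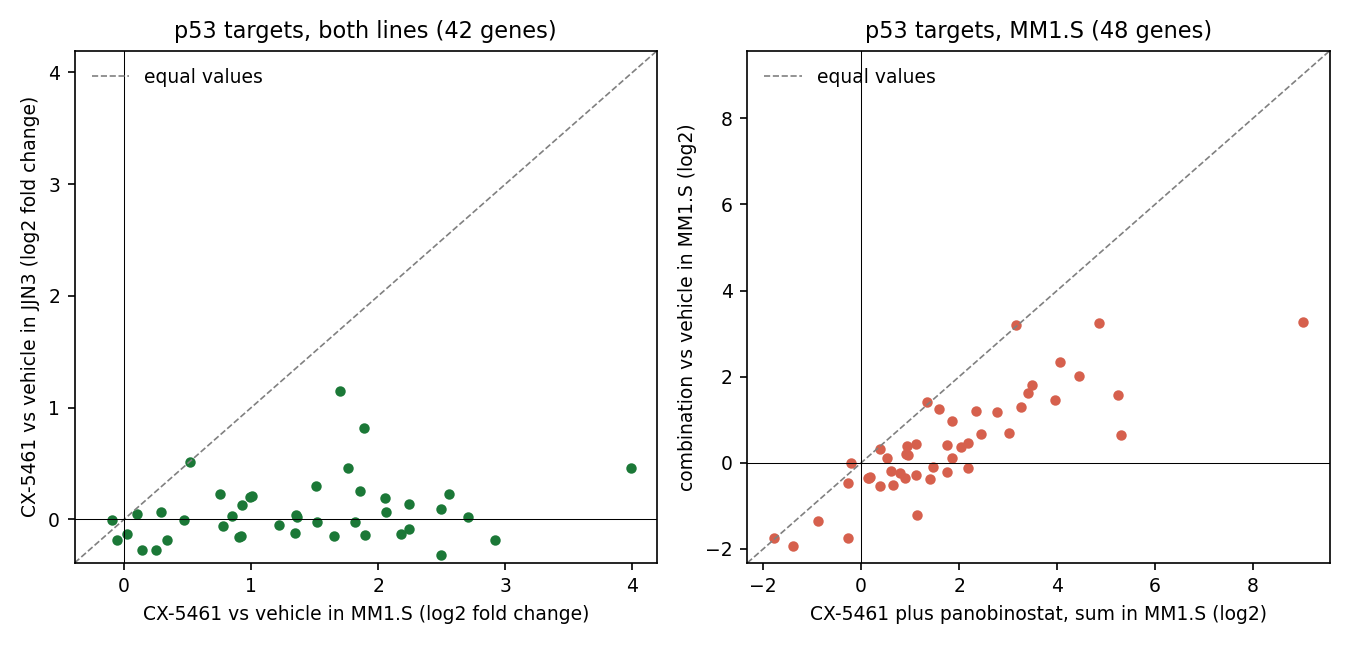
Log2 fold changes of p53 targets, 1 point per gene. Left, CX-5461 against vehicle in MM1.S (x) and JJN3 (y), 42 genes. Right, the sum of the single drugs (x) and the combination (y) in MM1.S, 48 genes, with the dashed line at equal values. Most points lie below the line in both panels. Genes absent from 1 group are not drawn.

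Panobinostat lowered genes of plasma cell identity and raised immediate early genes in MM1.S. Of 20 plasma cell identity genes 15 fell and 2 rose, also adjusted over the list alone (median log2 fold change -2.20, camera adjusted p = 1.92e-19, adjusted p = 0.0199 with an estimated correlation). TNFRSF17 (NCBI Gene 608), which encodes the plasma cell surface receptor BCMA, fell from 474 ± 49.6 to 3.92 ± 0.436 CPM (SD, n = 3, log2 fold change -6.90 ± 0.17, edgeR adjusted p = 1.79e-20), XBP1 (NCBI Gene 7494), the transcription factor of secretory cells, from 2496 ± 139.8 to 170 ± 28.8 CPM, and POU2AF1, a B cell coactivator, from 376 ± 23.9 to 17.7 ± 1.00 CPM. The chemokine receptor CXCR3 (-6.17 ± 0.26), SYCP3 of the synaptonemal complex (-5.77 ± 0.21), CRYBB1 (-5.66 ± 0.28) and the Fc receptor FCMR (-5.60 ± 0.17) had the next largest falls. The genes with the largest rises had 0 counts over the vehicle libraries: TMEM59L rose at least 331-fold (974 counts with panobinostat), the Notch ligand DLL3 at least 238-fold, the metallothioneins MT1E and MT1G at least 163-fold and 143-fold, and GPC2 at least 140.5-fold. Of 28 neuronal genes 21 were higher and 4 lower, also adjusted over the list alone (median 3.27, camera adjusted p = 5.89e-07, adjusted p = 0.135 with an estimated correlation). The expression filter keeps genes silent with vehicle only where another group expresses them, which favours rises in such a list. SYT11, a synaptotagmin, rose from 1.39 ± 0.627 to 107 ± 2.84 CPM. Of 20 immediate early genes 16 rose and 4 fell, also adjusted over the list alone (median 2.78, camera adjusted p = 1.74e-07, adjusted p = 0.0283 with an estimated correlation). IER2 rose from 11.2 ± 1.13 to 173 ± 20.7 CPM. Linker and replacement histones and other genes often raised by HDAC inhibitors were higher for 21 of 23 members and lower for 2, also adjusted over the list alone (median 2.44, camera adjusted p = 4.01e-10, adjusted p = 0.0907 with an estimated correlation). The medians of these lists were the same to 2 decimals with genes absent from 1 group at their bound. MALAT1, a nuclear long noncoding RNA, took 6.44% ± 0.980 of the counts with panobinostat and 0.542% ± 0.0899 with vehicle (SD, n = 3).

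Genes of growth and division were lower with panobinostat in MM1.S. MYC fell from 42.5 ± 9.75 to 3.57 ± 1.27 CPM (SD, n = 3, log2 fold change -3.56 ± 0.23, edgeR adjusted p = 1.24e-12), and 37 of 43 MYC targets were lower and 2 higher (median -1.26, camera adjusted p = 2.37e-11, adjusted p = 0.0855 with an estimated correlation). Of 49 replication genes 44 were lower and 0 higher (median -1.39, camera adjusted p = 1.36e-14, adjusted p = 0.135 with an estimated correlation). E2F2 fell from 249 ± 31.0 to 14.4 ± 1.08 CPM. Of 50 mitotic genes 45 were lower and 0 higher (median -1.40, camera adjusted p = 6.52e-15, adjusted p = 0.174 with an estimated correlation). FOXM1, a transcription factor of mitotic genes, fell from 103 ± 8.69 to 10.8 ± 1.59 CPM. Of 68 ribosome biogenesis genes 64 were lower and 0 higher (median -1.11, camera adjusted p = 1.30e-12, adjusted p = 0.135 with an estimated correlation). MRTO4 fell from 87.4 ± 8.76 to 9.92 ± 2.18 CPM, and UBTF fell from 181 ± 22.9 to 33.0 ± 4.03 CPM, while the RNA polymerase I machinery as a list was split, 6 higher and 10 lower of 20 (camera adjusted p = 0.313). These counts were the same adjusted over the list alone. Targets of p53 went both ways, 22 higher and 14 lower of 49 (camera adjusted p = 0.313). CDKN1A was at 1.25 ± 0.13, BBC3 at 0.77 ± 0.11 and MDM2 at -0.94 ± 0.14 on the log2 scale. Among regulators of apoptosis BCL2 fell, with a log2 fold change of -1.25 ± 0.16, and MCL1 and BCL2L11 (BIM) rose, by 0.88 ± 0.09 and 1.31 ± 0.17. Panobinostat against vehicle in MM1.S gave 8399 calls by edgeR among 12030 genes, 4439 higher and 3960 lower, 2634 and 1946 of them at least 2-fold. Library size alone as scaling shifted the median of all genes by 0.14 on the log2 scale against TMM, and 8384 were called without the 10 most abundant genes.

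Panobinostat raised neuronal genes in JJN3 as well. Of 18 neuronal genes tested 12 rose and 0 fell, also adjusted over the list alone (camera adjusted p = 8.26e-14, adjusted p = 0.00366 with an estimated correlation). As in MM1.S, the expression filter favours rises in this list, with panobinostat and with the combination. SYT11 rose from 5.87 ± 1.30 to 48.9 ± 12.1 CPM (SD, n = 3). TUBB3, a tubulin of neurons, rose from 0.399 ± 0.179 to 17.9 ± 11.2 CPM (edgeR adjusted p = 8.75e-04) and APLP1 from 0.942 ± 0.236 to 26.0 ± 13.1 CPM. HPCAL4, a neuronal calcium sensor, had 1 count over the vehicle libraries and 231 with panobinostat, a ratio of 250.5 (95% counting interval 44.5 to 9938). Genes often raised by HDAC inhibitors were higher for 14 of 22 members and lower for 0, or 15 and 0 adjusted over the list alone (median 0.66, camera adjusted p = 1.06e-09, adjusted p = 0.127 with an estimated correlation). Of 8 MHC class II genes 5 were higher and 0 lower, or 7 and 0 adjusted over the list alone (camera adjusted p = 0.00690, adjusted p = 0.284 with an estimated correlation). Ribosome biogenesis genes were lower for 37 of 68 members and higher for 0, or 46 and 0 adjusted over the list alone (median -0.53, camera adjusted p = 8.26e-14, adjusted p = 0.238 with an estimated correlation). NCL fell from 702 ± 23.6 to 327 ± 21.8 CPM and UBTF from 134 ± 26.8 to 68.1 ± 4.07 CPM. MYC targets were lower for 19 of 43 members and higher for 1, or 20 and 1 adjusted over the list alone (camera adjusted p = 2.35e-08, adjusted p = 0.115 with an estimated correlation). CAD, an enzyme of pyrimidine synthesis, was at -1.69 ± 0.20. Integrated stress response targets were lower for 21 of 39 members and higher for 0, or 23 and 0 adjusted over the list alone (median -0.50, camera adjusted p = 3.82e-06, adjusted p = 0.270 with an estimated correlation). Of 20 plasma cell identity genes 8 were lower and 1 higher, or 10 and 2 adjusted over the list alone (median -0.30, camera adjusted p = 0.00701, adjusted p = 0.301 with an estimated correlation). XBP1 fell from 853 ± 33.9 to 501 ± 39.3 CPM and IRF4 was at -0.90 ± 0.16. CDKN1A rose from 26.0 ± 3.70 to 61.3 ± 9.64 CPM (edgeR adjusted p = 2.15e-04), whereas the p53 targets as a list did not pass, with 8 of 43 higher and 3 lower, a median of -0.02, a mean of 0.25 and a test pointing up (camera adjusted p = 0.977). The receptor F2RL3 had the largest fall by the rule, from 22.5 ± 3.02 to 4.70 ± 1.14 CPM. Of 11411 genes edgeR called 2964, 1716 higher and 1248 lower, 4784 with the replicate number as a block (2561 and 2223), 1957 without panobinostat replicate 1, and 2950 without all 4 libraries of replicate 2.

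The response to panobinostat differed between the lines for plasma cell identity genes and for mitotic genes. The log2 fold change in JJN3 minus that in MM1.S was above 0 for 14 of 21 plasma cell identity genes and below 0 for 2, or 14 and 3 adjusted over the list alone (median 2.24, camera adjusted p = 2.48e-24, adjusted p = 5.37e-04 with an estimated correlation). It was above 0 for 48 of 50 mitotic genes and below for 0, also adjusted over the list alone (median 1.29, camera adjusted p = 3.67e-27, adjusted p = 0.0701 with an estimated correlation). It was below 0 for 13 of 23 genes often raised by HDAC inhibitors and above for 2, or 14 and 2 adjusted over the list alone (median -1.87, camera adjusted p = 1.01e-05, adjusted p = 0.232 with an estimated correlation). Among single genes the difference was 2.78 ± 0.40 for MYC, 1.49 ± 0.21 for UBTF and 1.78 ± 0.21 for BCL2. The test of the difference called 4284 of 12872 genes in edgeR, 2433 above 0 and 1851 below. With library size alone as scaling, which shifted the median of all genes by -0.13, the split was 1994 and 2270. Of 10628 genes tested in both lines, 1159 rose in both, against 525.9 for independent lists of the same length, 1033 fell in both, against 414.1, and 39 and 120 were called in opposite directions (Fisher's exact test, one-sided, p = 1.63e-285 for the genes that rose, with genes not independent). With the replicate number as a block in both lines 1656 rose and 1713 fell in both, against 820.1 and 768.2. Over the 10628 genes the log2 fold changes of the lines correlated (0.631), with a slope of JJN3 on MM1.S of 0.353. Changes were thus smaller in JJN3 over all genes, which may be part of the differences for lists that moved far in MM1.S. A difference beyond this slope was not tested.

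**Figure D3:**
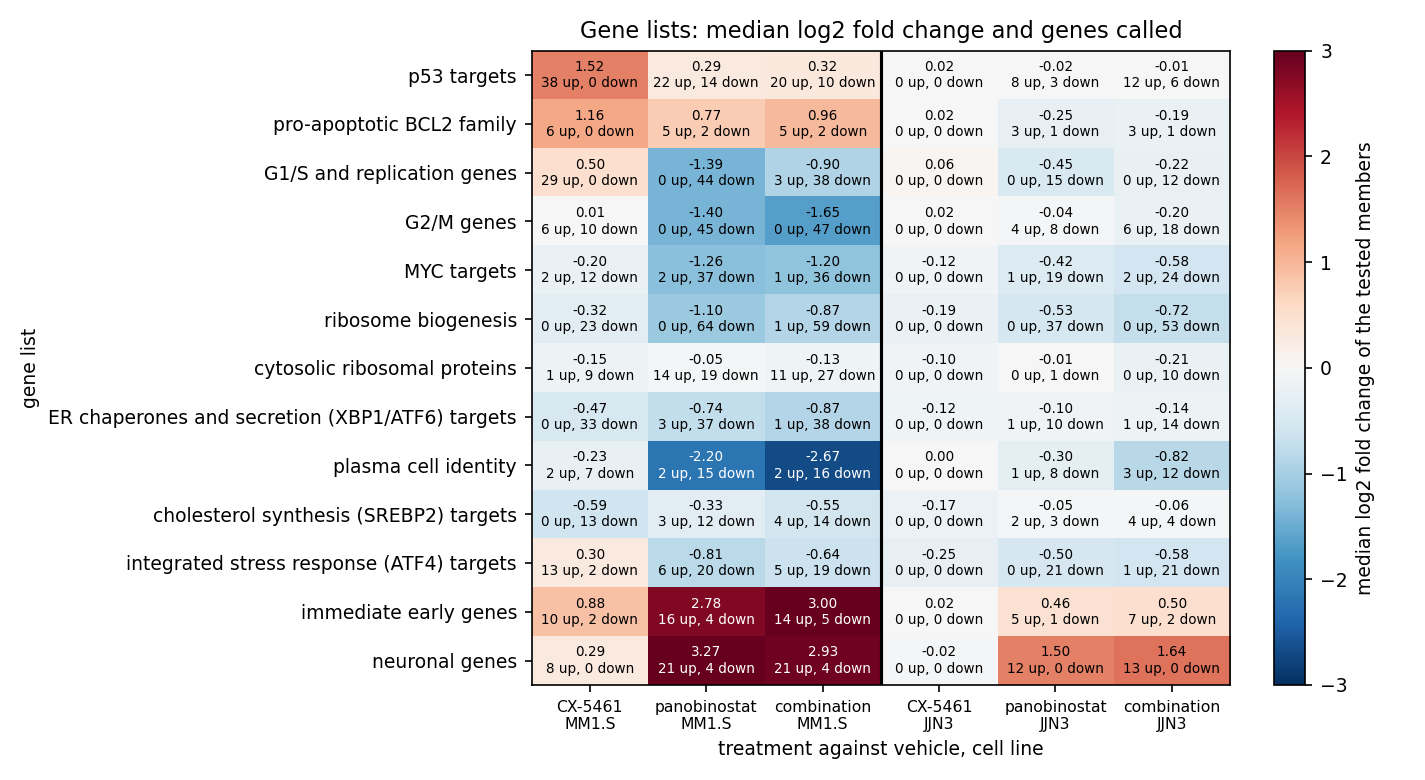
Median log2 fold change (colour) of 13 gene lists in the 6 comparisons of a treatment with vehicle, with the numbers of members called higher and lower written in each cell. The p53 targets have their highest median, 1.52, with CX-5461 in MM1.S, and the plasma cell list its lowest, -2.67, with the combination in MM1.S.

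With both drugs in MM1.S, genes of plasma cell identity fell, genes of mitosis were lower, and immediate early genes rose. Of 20 plasma cell identity genes 16 fell and 2 rose, also adjusted over the list alone (median log2 fold change -2.67, camera adjusted p = 2.61e-22, adjusted p = 0.0141 with an estimated correlation). TNFRSF17 fell from 474 ± 49.6 to 2.83 ± 1.08 CPM (SD, n = 3, log2 fold change -7.36 ± 0.18) and XBP1 to 136 ± 6.81 CPM. Of 50 mitotic genes 47 were lower and 0 higher, also adjusted over the list alone (median -1.65, camera adjusted p = 2.18e-20, adjusted p = 0.137 with an estimated correlation). FOXM1 was at -3.44 ± 0.13 and CCNB1 at -3.05 ± 0.17. MYC fell from 42.5 ± 9.75 to 1.67 ± 0.330 CPM and IRF4 had a log2 fold change of -1.58 ± 0.11. Of 49 p53 targets 20 were higher and 10 lower, also adjusted over the list alone (median 0.32, camera adjusted p = 0.0415, adjusted p = 0.186 with an estimated correlation), a call that also ended without the expression filter (0.155), with the stricter filter (0.0517), with limma-voom (0.0994) and without vehicle replicate 1 (0.0670). CDKN1A rose from 46.0 ± 6.60 to 138 ± 11.4 CPM and BBC3 from 80.6 ± 12.7 to 197 ± 8.46 CPM. TMEM59L rose at least 417-fold and DLL3 at least 293-fold. Among anti-apoptotic genes BCL2L1 (-3.52 ± 0.19) and BIRC5 (-2.51 ± 0.15), survivin, fell, as did 6 of 9 in the list, with 3 higher, also adjusted over the list alone (median -1.54, camera adjusted p = 0.0223, adjusted p = 0.292 with an estimated correlation, 0.0994 with limma-voom). Of 20 immediate early genes 14 rose and 5 fell, also adjusted over the list alone (median 3.00, camera adjusted p = 6.42e-07, adjusted p = 0.0354 with an estimated correlation). NR4A2 was at 6.02 ± 0.27. The number of genes called by edgeR was 8442 of 12030, 4447 higher and 3995 lower, 2668 and 1939 of them at least 2-fold. Library size alone as scaling shifted the median of all genes by 0.17, and 8431 were called without the 10 most abundant genes.

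With both drugs in JJN3, neuronal genes rose and genes of plasma cells and of ribosome production were lower. Of 18 neuronal genes 13 rose and 0 fell, or 14 and 0 adjusted over the list alone (median log2 fold change 1.64, camera adjusted p = 3.17e-10, adjusted p = 0.0102 with an estimated correlation), TUBB3 rose from 0.399 ± 0.179 to 66.0 ± 36.5 CPM (SD, n = 3), and HPCAL4 had 542 counts against 1, a ratio of 517 (95% counting interval 92.4 to 20460). Of 20 plasma cell identity genes 12 were lower and 3 higher, or 13 and 3 adjusted over the list alone (median -0.82, camera adjusted p = 4.00e-07, adjusted p = 0.105 with an estimated correlation). XBP1 fell from 853 ± 33.9 to 288 ± 9.59 CPM and MZB1, a chaperone of immunoglobulin assembly, had a log2 fold change of -1.76 ± 0.15. Of 68 ribosome biogenesis genes 53 were lower and 0 higher, or 58 and 0 adjusted over the list alone (median -0.72, camera adjusted p = 1.97e-13, adjusted p = 0.245 with an estimated correlation). NCL was at -1.61 ± 0.11 and UBTF at -1.39 ± 0.15. CDKN1A rose from 26.0 ± 3.70 to 106 ± 14.4 CPM (edgeR adjusted p = 6.82e-07), while MDM2 and BBC3 were at -0.39 ± 0.16 and -0.50 ± 0.20. Neither passed in edgeR with all libraries and the default filter (adjusted p = 0.0601 and 0.0537). Both passed as falls with the block (0.00374 and 2.14e-05), without the expression filter (0.0326 and 0.00115) and with the stricter filter (0.0460 and 0.0443). MDM2 also passed with limma-voom (0.0491), without vehicle replicate 1 (0.0474) and without combination replicate 3 (0.0135). BBC3 also passed with RLE (0.0490), with DESeq2 (0.0419), with the compared groups alone (0.0412), without vehicle replicate 3 (0.0105) and without combination replicate 2 (0.0273). Of 43 p53 targets 12 were higher and 6 lower, or 12 and 7 adjusted over the list alone, with a median of -0.01, a mean of 0.34 and a test pointing up (camera adjusted p = 0.609). The receptor F2RL3 (-3.55 ± 0.26), AGMAT (-3.36 ± 0.34) and CALN1 (-2.99 ± 0.19) were among the largest falls. Calls by edgeR numbered 4472 of 11411 genes, 2400 higher and 2072 lower, 1325 and 611 of them at least 2-fold. With library size alone as scaling, which shifted the median of all genes by 0.11, the split was 2943 and 1539, and 4440 were called without the 4 libraries of replicate 2.

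The effect of the combination differed between the lines for mitotic and plasma cell genes. In JJN3 minus MM1.S, 46 of 50 mitotic genes were above 0 and 0 below, or 47 and 0 adjusted over the list alone (median 1.51, camera adjusted p = 3.10e-36, adjusted p = 0.0256 with an estimated correlation). CCNB1 was at 2.61 ± 0.24. Of 21 plasma cell identity genes 14 were above 0 and 3 below, or 15 and 3 adjusted over the list alone (median 1.91, camera adjusted p = 3.14e-19, adjusted p = 0.00198 with an estimated correlation). For MYC the difference was 3.49 ± 0.45, for BCL2 2.05 ± 0.21, for BBC3 -1.77 ± 0.23 and for DDIT3 -2.99 ± 0.33. Of 12872 genes edgeR called 4223, 2422 above 0 and 1801 below. Among 10628 genes tested in both lines, 1623 rose with the combination in both, against 755.2 for independent lists, 1547 fell in both, against 684.2, and 102 and 185 were called in opposite directions. Their log2 fold changes had a slope of JJN3 on MM1.S of 0.432. As with panobinostat, smaller changes in JJN3 over all genes may be part of the differences for these lists.

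Adding CX-5461 to panobinostat in MM1.S raised p53 targets and the polyA-selected reads of replication-dependent histone genes. Against panobinostat alone, 10 of 49 p53 targets rose and 1 fell, or 18 and 4 adjusted over the list alone (median log2 fold change 0.22, camera adjusted p = 1.94e-06, adjusted p = 0.0302 with an estimated correlation). MDM2 rose from 181 ± 35.2 to 473 ± 79.0 CPM (SD, n = 3) and PHLDA3 by 1.65 ± 0.29 on the log2 scale. Of 10 replication-dependent histone genes 6 rose and 0 fell, or 7 and 0 adjusted over the list alone (median 1.36, camera adjusted p = 2.69e-12, adjusted p = 0.0302 with an estimated correlation). Histone transcripts without a polyA tail were not measured, and values of histone genes are uncertain, so total histone transcripts may differ. Replication genes were higher for 19 of 49 members and lower for 0, or 29 and 0 adjusted over the list alone (camera adjusted p = 7.64e-26, adjusted p = 0.109 with an estimated correlation), and mitotic genes lower for 11 of 50 and higher for 1, or 21 and 2 adjusted over the list alone (camera adjusted p = 5.71e-11, adjusted p = 0.386 with an estimated correlation). PLK1, a mitotic kinase, fell from 8.44 ± 1.47 to 1.75 ± 1.04 CPM and CCNB1 was at -1.30 ± 0.19. IRF4 fell (-0.75 ± 0.11), and BBC3 (0.52 ± 0.11) and DDIT3 (1.00 ± 0.17) rose. In all, edgeR called 491 genes, 293 higher and 198 lower. With library size alone as scaling the split was 401 and 150. The count depended on single libraries: it was 1177 without panobinostat replicate 1, 229 without panobinostat replicate 2, 175 without panobinostat replicate 3, 197 without combination replicate 1 and 215 without combination replicate 3.

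Adding panobinostat to CX-5461 in MM1.S lowered p53 targets. Against CX-5461 alone, 36 of 49 p53 targets fell and 6 rose, also adjusted over the list alone (median log2 fold change -1.15, camera adjusted p = 9.24e-07, adjusted p = 0.0222 with an estimated correlation). CDKN1A fell from 734 ± 47.6 to 138 ± 11.4 CPM (SD, n = 3, log2 fold change -2.41 ± 0.12, edgeR adjusted p = 1.11e-14), and MDM2 and BBC3 had log2 fold changes of -1.61 ± 0.14 and -1.20 ± 0.11. Plasma cell identity genes fell, 18 of 20 with 1 higher, also adjusted over the list alone (median -2.46, camera adjusted p = 1.22e-19, adjusted p = 0.0222 with an estimated correlation), and 14 of 20 immediate early genes rose with 4 lower, also adjusted over the list alone (median 1.79, camera adjusted p = 6.65e-05, adjusted p = 0.0222 with an estimated correlation). In all, edgeR called 8393 genes, 4320 higher and 4073 lower. In JJN3 the same comparison called 3922 genes, 2141 higher and 1781 lower, with 13 of 18 neuronal genes higher and 1 lower, or 15 and 1 adjusted over the list alone (median 1.55, camera adjusted p = 3.98e-11, adjusted p = 0.00959 with an estimated correlation), CDKN1A rising from 36.0 ± 10.9 to 106 ± 14.4 CPM and IRF4 falling from 216 ± 29.0 to 87.3 ± 15.3 CPM.

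With CX-5461 added to panobinostat in JJN3, plasma cell identity genes were lower, 8 of 20 with 0 higher, or 9 and 0 adjusted over the list alone (median log2 fold change -0.51, camera adjusted p = 8.63e-11, adjusted p = 0.0719 with an estimated correlation). With the replicate number as a block, MYC targets (0.00754), mitotic genes (0.0463), ER secretion genes (0.0467) and replication-dependent histones (0.0458) were also lower by camera's adjusted p, and genes often raised by HDAC inhibitors (0.00740) and neuronal genes (0.0383) higher. ANK3, an ankyrin, fell, at -1.51 ± 0.21 (edgeR adjusted p = 0.00353, 0.0531 without combination replicate 1). In all, edgeR called 103 genes, 21 higher and 82 lower, and 1399 with the block (659 and 740). With library size alone as scaling the split was 59 and 56. Without combination replicate 1 it called 0, without panobinostat replicates 1, 2 or 3 it called 57, 22 and 65, and without combination replicate 3 it called 51. At an unadjusted p under 0.05 all libraries gave 1611, and DESeq2 called 255.

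Together the drugs changed p53 targets of MM1.S by less than the sum of their single effects. The departure from additivity was below 0 for 30 of 49 p53 targets and above 0 for 0, or 36 and 0 adjusted over the list alone (median -1.35, camera adjusted p = 1.17e-57, adjusted p = 8.66e-06 with an estimated correlation). CDKN1A was at -3.66 ± 0.18 (edgeR adjusted p = 6.33e-13), BBC3 at -1.97 ± 0.15, GDF15 at -5.75 ± 0.63 and ARVCF, a catenin, at -5.79 ± 0.58. The departure was below 0 for 3 of 9 pro-apoptotic BCL2 family genes and above for 0, or 4 and 1 adjusted over the list alone (median -1.02, camera adjusted p = 6.66e-08, adjusted p = 0.00459 with an estimated correlation). Interferon-stimulated genes departed below 0 for 9 of 35 members and above for 0, or 13 and 0 adjusted over the list alone (median -0.60, camera adjusted p = 6.36e-08, adjusted p = 0.00459 with an estimated correlation), and immediate early genes for 7 of 20 and 0, or 10 and 0 adjusted over the list alone (median -0.96, camera adjusted p = 2.06e-08, adjusted p = 0.00459 with an estimated correlation). Ribosome biogenesis genes were above 0 for 23 of 68 members and below for 0, or 44 and 0 adjusted over the list alone (median 0.59, camera adjusted p = 1.25e-25, adjusted p = 0.0554 with an estimated correlation), and among single genes METTL1, an RNA methyltransferase, was at 1.86 ± 0.33. In all, edgeR called 664 genes, 225 above 0 and 439 below, against 438 without CX-5461 replicate 1, 1042 without panobinostat replicate 1, 415 without panobinostat replicate 3 and 418 without combination replicate 1. Of the genes called with each drug alone in MM1.S, 541 rose with both, 522 fell with both and 496 were called in opposite directions, against 429.9, 279.5 and 696.8 for independent lists. Simulations of unchanged groups gave 0.02, 0.02 and 0. Without any drug effect almost no gene is called, so the simulations set no chance level for these overlaps. With library size alone as scaling 761 rose and 300 fell with both, against 645.2 and 144.3 for independent lists. The covariance of the log2 fold changes was 0.417, against 0.0787 simulated, and their correlation 0.360, against 0.529 simulated. The 3 vehicle libraries cannot be split, so part of the excess may come from the shared vehicle.

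In JJN3 edgeR called 0 genes for departure from additivity, with 564 at an unadjusted p under 0.05, 21 by DESeq2 (2 above and 19 below), 0 by limma-voom, 105 with the replicate number as a block (14 and 91) and 1 without CX-5461 replicate 2. Plasma cell identity genes lay below 0 as a list with 0 of 20 called, or 6 below adjusted over the list alone (median -0.38, camera adjusted p = 9.35e-09, adjusted p = 0.0816 with an estimated correlation), and cholesterol synthesis genes above 0 with 0 of 23 called, also adjusted over the list alone (median 0.31, camera adjusted p = 2.74e-04, adjusted p = 0.0816 with an estimated correlation). In JJN3 0 genes were called with both single drugs, since 0 were called with CX-5461. With the replicate number as a block 43 rose and 55 fell with both, against 15.5 and 17.1 for independent lists, and 7 and 7 were called in opposite directions. Both drugs share the vehicle libraries and the fit with the block was not simulated, so part of this excess may come from the shared vehicle. Without the expression filter 7 rose and 10 fell with both, and with DESeq2 1 and 9. The covariance of the log2 fold changes was 0.119, against 0.0634 simulated, and their correlation 0.361, against 0.494 simulated.

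**Figure D4:**
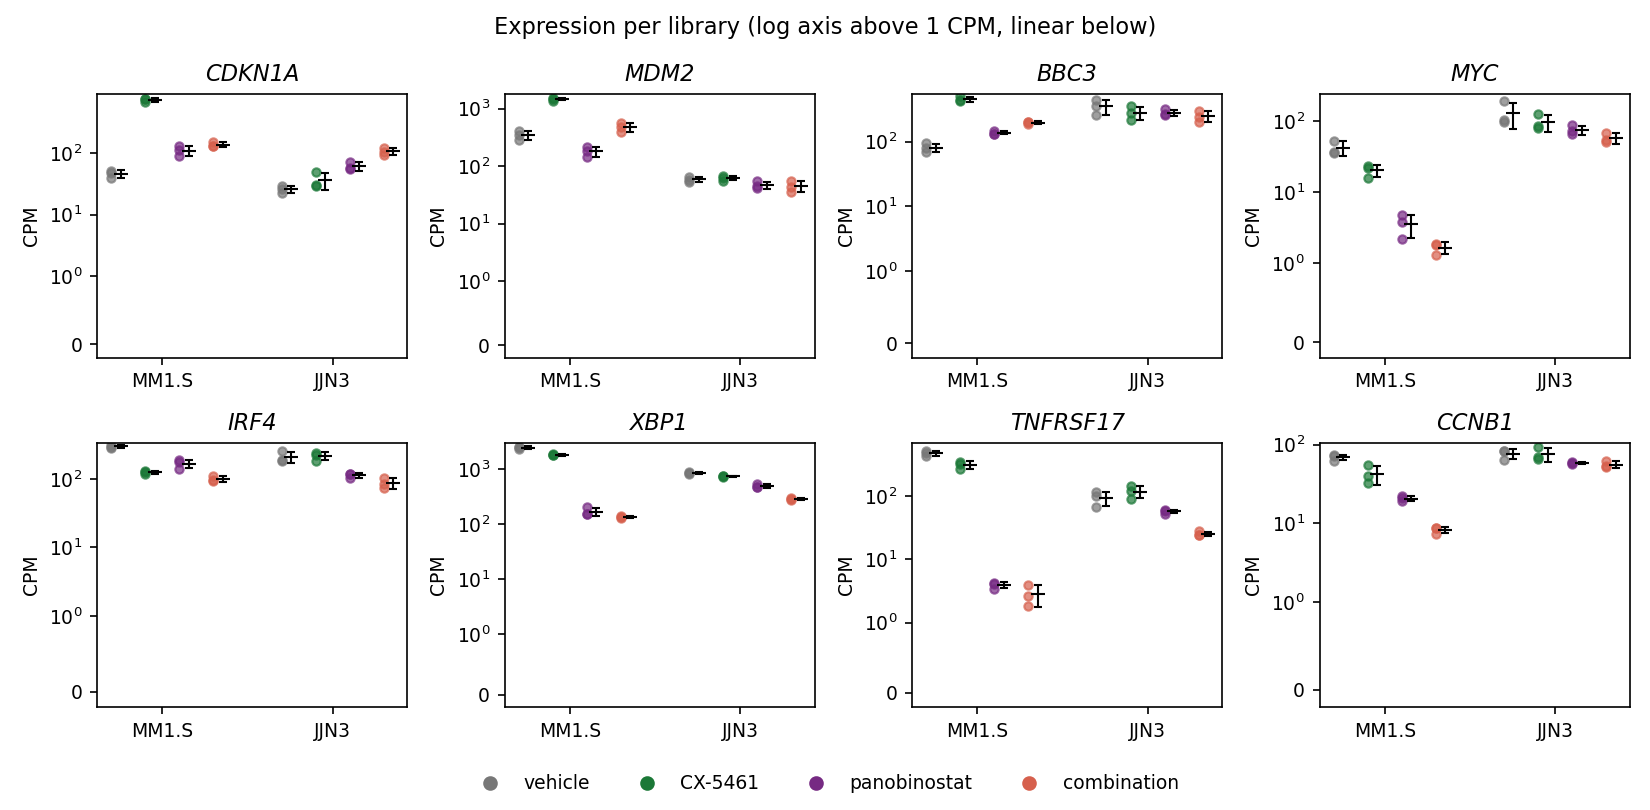
CPM of CDKN1A, MDM2, BBC3, MYC, IRF4, XBP1, TNFRSF17 and CCNB1 in each library (points) with the mean and SD of the 3 libraries of a group (dash and bar), on an axis that is linear below 1 CPM and logarithmic above. CDKN1A in MM1.S lies at 46.0 CPM with vehicle, 734 with CX-5461, 110 with panobinostat and 138 with the combination.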

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

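The tests of precision in JJN3, of an effect of CX-5461 on the JJN3 libraries, of leaking RNA and of a ceiling, and the sorting of sample splits by the drug or line they follow, were chosen after the results were seen.

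The p53 targets rose with CX-5461 in MM1.S, and of the same 38 genes, 32 of which were tested in JJN3, 0 were called there. Lower precision in JJN3 is argued against by their median log2 fold change there, 0.0503 (quartiles -0.09 and 0.23, range -0.32 to 5.04) over the 32 tested, against 1.79 in MM1.S. The 95% interval of the difference between the lines lay below 0 for 29 of the 38. The 38 were chosen in the same MM1.S libraries, which favours large values there and intervals below 0. The test of the difference over all p53 targets, given above, is free of this choice. Whether CX-5461 had any effect on the JJN3 libraries was not decided by splits of the 6 libraries. With the replicate number as a block 157 genes were called, against 0 in the other splits that part all pairs. There are 4 such splits in all, too few for a share under 0.05, and the others mix treated and vehicle libraries. Without the block the real split called 0 genes and another split called 20. The label of JJN3 as p53 null leaves a loss of p53 as a candidate explanation. With 1 line of each kind, other differences between the lines stay open, and a role of p53 may be a hypothesis only.

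MALAT1 rose with panobinostat in MM1.S, by 3.43 ± 0.12 on the log2 scale (edgeR adjusted p = 5.34e-17), and was at 0.64 ± 0.34 in JJN3 (edgeR adjusted p = 0.202). In a fit without the 10 most abundant genes, 8353 of the 8382 remaining called genes, 99.65%, kept their call and direction. That fit was again scaled by TMM, which trims genes with extreme levels or changes, so this outcome was largely fixed. It does not decide whether a few abundant genes set the calls of the others. With library size alone as scaling 5027 genes were higher and 3411 lower, in place of 4439 and 3960, and the median of all genes shifted by 0.14. Leaking cytoplasmic RNA from dying cells was examined through the mitochondrially encoded transcripts. Their median was 0.15 (quartiles 0.04 and 0.38, 15 genes), far from the change of MALAT1. Mitochondrial reads took 6.21% ± 0.642 of the counts with panobinostat and 4.98% ± 0.344 with vehicle (SD, n = 3). Viability was not analysed, and whether these transcripts track leakage was not tested, so they do not decide. A larger share of nuclear RNA cannot be told apart from changes of single genes: the median of 5 other RNAs retained in the nucleus was 0.39, with NEAT1 (2.67), KCNQ1OT1 (1.74) and TUG1 (0.39) higher, PVT1 (-1.63) lower and MIAT (-0.54) not passing. A direct effect of panobinostat on MALAT1 stays open and was not tested.

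The p53 targets of MM1.S rose less with the combination than the sum of the single drugs. A ceiling already reached with panobinostat is argued against by the fall of these 38 genes from CX-5461 to the combination, with a median log2 fold change of -1.23 (quartiles -2.25 and -0.88, 32 called lower), and by their median of 0.19 with panobinostat alone and 0.38 with the combination against vehicle. The 38 were chosen as higher in the same CX-5461 libraries, which favours a fall from those libraries to the combination. The fall over all p53 targets, given above, is free of this choice. With library size alone as scaling, 29 of 30 targets below additivity kept the call. That scaling shifted the median departure of all genes by -0.04, further below 0, so it could hardly end these calls and the test does not decide. RLE shifted it the other way, by 0.02. Both shifts were far smaller than the median departure of the p53 targets given above. The call of MDM2 ended with RLE (edgeR adjusted p = 0.052) and with library size alone (0.0742). Protein levels of p53 were not analysed here, so changes of its amount or of chromatin at the targets stay open.

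For CX-5461 the effect differed between JJN3 and MM1.S, by the test of the difference itself, for 170 genes. Of 16 lists called for this difference 4 kept the call with an estimated correlation, with a median of -1.30 for p53 targets, -0.66 for pro-apoptotic BCL2 family genes, -0.42 for NF-kB targets (3 of 22 below 0 and 0 above, or 5 and 1 adjusted over the list alone, camera adjusted p = 9.36e-05, adjusted p = 0.0148 with an estimated correlation) and 0.33 for cholesterol synthesis genes. Single genes differed by 3.20 (RAB36), 2.03 (PIF1), 1.54 (GCSAM), -5.53 (GDF15), -4.36 (PHLDA3), -4.31 (NRP2), -3.53 (CDKN1A), -1.99 (MDM2), -2.81 (BBC3), 1.31 (IRF4) and -3.28 (DDIT3). The call of GCSAM ended without MM1.S vehicle replicate 3 (edgeR adjusted p = 0.0542), MM1.S CX-5461 replicate 3 (0.0629), JJN3 vehicle replicate 2 (0.0700), JJN3 vehicle replicate 3 (0.0621) or JJN3 CX-5461 replicate 1 (0.0501), or with limma-voom (0.0533), that of GDF15 without JJN3 vehicle replicate 1 (0.134) and that of PHLDA3 without JJN3 vehicle replicate 3 (0.102).

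For panobinostat the effect differed for 4284 genes. Of 13 lists called for this difference 1 kept the call with an estimated correlation, plasma cell identity, with a median of 2.24. Single genes differed by 6.87 (DSP), 6.60 (PVRIG), 6.33 (CD40), -10.71 (DLL3), -9.10 (CGREF1), 0.62 (MDM2), -1.07 (BBC3), 2.78 (MYC), -0.72 (HDAC6), 1.49 (UBTF), 1.26 (TOP2A), 0.68 (TOP2B), -0.83 (BCL2L11), 1.78 (BCL2), -0.61 (MCL1), 1.37 (CCNB1) and -1.80 (DDIT3). The call of MDM2 ended without MM1.S vehicle replicate 1 (edgeR adjusted p = 0.0671) or 3 (0.147), MM1.S panobinostat replicate 1 (0.180) or 2 (0.0801), JJN3 vehicle replicate 1 (0.104), 2 (0.0736) or 3 (0.0539), or JJN3 panobinostat replicate 3 (0.150), and with library size alone as scaling (0.124) or DESeq2 (0.0522).

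For the combination the effect differed for 4223 genes. Of 13 lists called 2 kept the call with an estimated correlation, with a median of 1.51 for mitotic genes and 1.91 for plasma cell identity genes. Single genes differed by 12.18 (CCL3), 8.06 (DSP), 7.90 (CD40), -10.54 (CGREF1), -10.51 (DLL3), -8.85 (MAFA), -0.82 (MDM2), -1.77 (BBC3), 3.49 (MYC), -0.92 (HDAC6), 0.84 (UBTF), 1.33 (TOP2A), 0.79 (TOP2B), 2.05 (BCL2), 2.61 (CCNB1), -2.99 (DDIT3) and 1.02 (HMGCS1). The call of CCL3 ended without JJN3 combination replicate 3 (edgeR adjusted p = 0.0521) or with limma-voom (0.0501). Fitted values of DSP, CD40, DLL3, CGREF1, MAFA and CCL3 are no bounds, because 1 of the groups compared holds 0 counts.

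Splits of the same libraries into other groups were counted for each test. With 3 libraries against 3 there are 10 splits, so the share of splits with as many calls is never under 0.1. Each split other than the real one mixes libraries of both groups, which puts a drug effect into the spread within groups. Few calls in those splits therefore set no chance level for the real one. The real split called 2014 genes for CX-5461 in MM1.S against at most 2 in another split, 8399 against 0 for panobinostat, 8442 against 0 for the combination, and 8393 against 0 for the combination against CX-5461. For the combination against panobinostat in MM1.S the real split called 491 and another called 463. In JJN3 the real split called 0 for CX-5461 and another called 20, so all 10 splits gave as many. It called 2964 against 0 for panobinostat, 4472 against 0 for the combination, 3922 against 0 for the combination against CX-5461 and 103 against 1 for the combination against panobinostat. With the replicate number as a block, the splits that part all pairs other than the real one called 0 genes in each of the 5 comparisons in JJN3, and the real one 157, 4784, 6104, 5593 and 1399. For additivity in MM1.S 1 of 100 splits, the real one, called 664 genes and the highest other 4. Most other splits mix libraries with and without panobinostat in a group, which widens the spread within groups, and only 9 follow the exposure to panobinostat, too few for a share under 0.05. For additivity in JJN3 the real split called 0, so all 100 gave as many, and 3 others that follow the exposure to panobinostat called genes, up to 4932. For the differences between the lines 6 of 50 splits called as many genes as the real 170 for CX-5461 (highest 864), 9 of 50 as many as 4284 for panobinostat (highest 7703) and 5 of 50 as many as 4223 for the combination (highest 6160). All of these keep the treated and vehicle libraries of 1 line whole, a structure of the samples, and the splits that do not called at most 1, 0 and 0 genes.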

How the results depend on the processing

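The list tests without single libraries and under other filters, the overlaps under other settings, and the fits without the 10 most abundant genes or without all JJN3 libraries of replicate 2 were chosen after seeing the data. Of 7102 values of named genes under an alternative, 6854 kept their direction and side of the threshold, 202 lost the call, 46 gained one and 0 reversed; 56 that were below the threshold changed sign. Of 7886 list tests 7243 kept their side, 343 lost the call, 298 gained one and 2 reversed. Of 202 list calls 30 held with an estimated correlation, while RLE gave 203, library size alone 197, no filter 228, the stricter filter 210, limma-voom 212, the block 215 and fry 241. The list of G1/S and replication genes with CX-5461 in JJN3 passed in the lower direction without JJN3 vehicle replicate 2 (camera adjusted p = 0.0197), pointed down without JJN3 CX-5461 replicate 3 (0.733) and up without each of the other 4 libraries, with the smallest p, 2.87e-05, without CX-5461 replicate 2. The list of immediate early genes passed in the lower direction without JJN3 CX-5461 replicate 2 (0.0284) and in the higher one without JJN3 vehicle replicate 2 (0.0190), with the highest value, 0.672, without JJN3 vehicle replicate 1, and the cause was not tested.

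Without the expression filter, 31 genes were called for CX-5461 in JJN3, 439 for the combination against panobinostat in JJN3, 46 for additivity in JJN3 and 310 for the CX-5461 difference between lines; with DESeq2 the first 3 were 18, 255 and 21. With only the compared groups in the fit, 246 were called for the combination against panobinostat in MM1.S. With the replicate number as a block the counts were 157 for CX-5461 in JJN3, 4784 for panobinostat in JJN3, 1399 for the combination against panobinostat in JJN3, 105 for additivity in JJN3 and 582 for the CX-5461 difference. Beyond the calls given beside the results, the block in JJN3 gained RPL12 (0.0463), ALDH1L2 (0.0192), EDEM3 (0.0493), ISG20 (0.0160), HLA-DQA1 (0.0160), HLA-DQB1 (0.0296) and MCL1 (0.0411) with CX-5461. With panobinostat it gained MDM2 (0.0156), BBC3 (0.00726), POLR1B (0.00492), MCL1 (0.00679), CCNB1 (0.00618) and the heat shock list (0.0432), and with the combination POLR1A (0.0351). It also gained ribosomal proteins for additivity in JJN3 (0.0210), plasma cell genes in the CX-5461 difference (0.00360) and p53 targets in that of the combination (0.0446). In MM1.S the correlations between libraries of the same number were -0.0474 to 0.290 (median 0.0699). For libraries of different numbers they were -0.2898 to 0.1455 (median -0.0377). A pairing by number was thus weaker than in JJN3 but cannot be excluded. The block gave 925 genes for the combination against panobinostat in place of 491, and 1023 for additivity in place of 664.

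Leaving out 1 library at a time gave 415 to 1042 genes for additivity in MM1.S, 175 to 1177 for the combination against panobinostat in MM1.S, 0 to 2 for CX-5461 in JJN3, 1957 to 2950 for panobinostat in JJN3, 0 to 1 for additivity in JJN3, 0 to 105 for the combination against panobinostat in JJN3 and 108 to 245 for the CX-5461 difference; CX-5461 in MM1.S gave 1347 to 1756 and stayed within 1.5 times, as did the other 7 comparisons. Overlaps between the lines for CX-5461 were 31 higher and 44 lower with the block, 6 and 6 without the filter and 3 and 6 with DESeq2.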

Other observations

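The tests of gene groups by level with a minimum of vehicle counts and of the direction in MM1.S of the genes called with the block were chosen after the results were seen.

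Lists that moved less with CX-5461 in MM1.S, each with its call lost with an estimated correlation, were those of protein synthesis and breakdown, respiration and lysosomes, among others. Cytosolic ribosomal protein genes were lower for 9 of 77 members and higher for 1, or 7 and 1 adjusted over the list alone (camera adjusted p = 1.05e-04, adjusted p = 0.537 with an estimated correlation), and proteasome subunits lower for 4 of 31 and higher for 0, or 1 and 0 adjusted over the list alone (camera adjusted p = 4.33e-04, adjusted p = 0.331 with an estimated correlation). Heat shock genes were lower for 9 of 24 and higher for 2, or 12 and 2 adjusted over the list alone (camera adjusted p = 1.36e-04, adjusted p = 0.136 with an estimated correlation). AHSA1, a cochaperone of HSP90, was at -0.75 ± 0.09. Nuclear genes of oxidative phosphorylation were lower for 10 of 53 and higher for 0, also adjusted over the list alone (camera adjusted p = 2.76e-04, adjusted p = 0.526 with an estimated correlation). NDUFV2 was at -0.77 ± 0.09. Lysosome and autophagy genes were higher for 8 of 31 and lower for 0, or 15 and 0 adjusted over the list alone (camera adjusted p = 0.00137, adjusted p = 0.0825 with an estimated correlation). SQSTM1, an autophagy receptor, was at 1.00 ± 0.18. The mitochondrially encoded genes passed narrowly with 2 of 15 lower and 0 higher, or 1 and 0 adjusted over the list alone (camera adjusted p = 0.0499, adjusted p = 0.556 with an estimated correlation), and not without vehicle replicate 1 (0.218) or CX-5461 replicate 2 (0.173). Neuronal genes were higher for 8 of 28 and lower for 0, also adjusted over the list alone (median 0.29, or 0.11 with 8 genes absent from 1 group at their bound, camera adjusted p = 0.00621, adjusted p = 0.324 with an estimated correlation) and genes often raised by HDAC inhibitors for 6 of 23 with 1 lower, also adjusted over the list alone (median 0.34, or 0.32 at the bounds, camera adjusted p = 9.08e-06, adjusted p = 0.136 with an estimated correlation). Topoisomerases, HDACs and sirtuins, MHC class I, glycolysis and replication-dependent histone genes did not pass (camera adjusted p = 0.522, 0.603, 0.795, 0.0993 and 0.778). Medians and tests differed in sign for topoisomerases (median 0.08, mean -0.04, test down), HDACs and sirtuins (median 0.01, mean 0.04, test down) and replication-dependent histones (median -0.36, mean 0.80, test up).

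With panobinostat in MM1.S, ER secretion genes were lower for 37 of 47 members and higher for 3 (median -0.74, camera adjusted p = 1.90e-07, adjusted p = 0.135 with an estimated correlation), proteasome subunits lower for 28 of 31 and higher for 1 (camera adjusted p = 7.41e-06, adjusted p = 0.237 with an estimated correlation), and MHC class I genes lower for 5 of 9 and higher for 1 (camera adjusted p = 0.00505, adjusted p = 0.0907 with an estimated correlation). PSMB10, a subunit of the immunoproteasome, was at -3.82 ± 0.12. Interferon-stimulated genes were higher for 21 of 35 and lower for 10 (camera adjusted p = 0.0139, adjusted p = 0.0907 with an estimated correlation). Lysosome genes were higher for 20 of 31 and lower for 4, or 21 and 4 adjusted over the list alone (camera adjusted p = 0.00154, adjusted p = 0.0938 with an estimated correlation). The counts of the other 4 of these lists were the same adjusted over the list alone. NF-kB targets went both ways, 8 higher and 7 lower of 21, with a median of -0.13, a mean of 0.06 and a test pointing down (camera adjusted p = 0.818).

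B cell markers and epithelial and stromal markers did not pass in MM1.S with panobinostat, with 5 of 8 higher and 1 lower (camera adjusted p = 0.177) and 4 of 8 higher and 2 lower (camera adjusted p = 0.556). Of T and NK cell, myeloid, and erythroid and megakaryocyte markers only 2, 3 and 3 were measured in MM1.S, too few for a test. In JJN3 with panobinostat B cell (0.561), epithelial and stromal (0.516), T and NK cell (0.623) and erythroid and megakaryocyte (0.0912) markers did not pass by camera's adjusted p. Long noncoding RNAs rose with panobinostat for 43.8% of 537 tested in MM1.S and fell for 21.8%, against 36.5% and 33.8% of 11189 protein-coding genes (medians 0.59 and 0.04), and in JJN3 for 27.7% and 3.42% of 527, against 14.4% and 11.5% of 10625 (medians 0.46 and -0.01). The difference between the classes was not tested.

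A hypothesis that panobinostat raises weakly expressed genes and lowers strongly expressed ones was tested by ranking genes by their vehicle level in the other line. In MM1.S the median log2 fold change of the lowest of 5 equal groups of genes minus that of the highest was 1.16, and in JJN3 it was 0.57, both of which point the way of the hypothesis. The expression filter keeps weakly expressed genes only where some group expresses them, which favours rises, so part of both differences may come from the filter. Among genes with at least 30 vehicle counts the differences were smaller, 0.65 (9731 genes) and 0.34 (9909 genes).

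Genes called with CX-5461 in JJN3 only with the replicate number as a block may respond in MM1.S as well. Of the 138 tested in both lines, 120 had the same direction in MM1.S, 86.96% (exact 95% interval 80.2 to 92.1%, exact binomial test, two-sided, p = 1.09e-19, with genes not independent), 66 of them called there in the same direction and 3 of the 138 in the opposite one. The direction was the same for 51 of 57 higher and 69 of 81 lower genes. The binomial test takes both directions as equally likely. Over all 10628 genes tested in both lines, however, the log2 fold changes of CX-5461 correlated between the lines (0.258). The share of all genes with the same direction was not counted, so the p-value does not measure an agreement particular to these genes.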
